A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

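RNA sequencing was done on 24 libraries of budding yeast strain CEN.PK: WT, rph1Δ, set2Δ and H3K36A cells, each at 0 h in rich medium (YPL) and at 1 h and 3 h after a wash and a move to minimal medium (SL), with 2 libraries in each of the 12 groups. Per the labels, RNA was extracted with a yeast RNA purification kit and libraries were made by an Illumina protocol. Whether replicates were separate cultures is not stated in the labels, so every p-value measures only the spread between these samples. Groups came from the sample labels, and each library was joined to its values by the sample title in the column header.

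The deposited table holds raw counts per gene, whole numbers summing to 6623458 to 7677684 per library, and, per the file headers, FPKM made by the authors from those counts. The FPKM values equalled the count scaled by exonic length and by the library's total for 100% of values (tolerance 0.0051). The submitters' processing notes name cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1 and genome build sacCer3, with no settings. How reads shared by near-identical genes or by overlapping genes were counted, and the strand of the reads, are not given in the sources used here. Of the 7126 genes in the table, 1420 overlap another gene, and this is said where such a gene is named. Positions are those of sacCer3 as listed in the table, where 6048 gene identifiers matched the reference annotation and 6036 had identical coordinates.

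The comparisons, tests, gene lists and rule for naming genes were fixed before the data were examined. That design took FPKM to be the only unit and named limma-trend on log2(FPKM + 1), with edgeR in its place if counts were found. Since counts were found, the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on counts with TMM scaling (factors 0.823 to 1.19) was used. All 12 groups were fitted together with no covariate, leaving 12 residual degrees of freedom. Genes with an FPKM of at least 1 in at least 2 libraries were tested (6503 genes, 623 left out). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The SE of a log2 fold change is its size divided by the square root of the F statistic, and the common biological coefficient of variation was 6.73%. The 21 comparisons were WT over time (3), each mutant against WT at each time (9), each mutant's change from 0 h less that of WT (6) and set2Δ against H3K36A at each time (3). Shared changes were counted for each pair of mutants at each time, and the covariance of their log2 changes was set beside 1000 draws simulated with unchanged mutants and shared WT libraries. In these draws the spread of a gene was the same in all groups. Where a group held 3 or fewer counts over its 2 libraries, counts are given in place of a fold change.

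Of 44 fixed lists of genes by pathway or process, 43 had at least 3 measured members and were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over 43 lists within each comparison. Each test was repeated with the correlation estimated. Where a single adjusted p under 0.05 is given for a list, its call held with the estimated correlation, and where it did not hold both are given. Counts of members are adjusted over all genes tested, and the count adjusted over the list alone is given where it differed. The list of 8 mitochondrial encoded genes had 1 measured member and was not tested. Ribosomal protein genes were taken by a name pattern that also took RPP1, a ribonuclease P subunit gene. The list counts include members of near-identical pairs, whose separate levels are uncertain.

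Named genes had an adjusted p under 0.05, an absolute log2 fold change of at least 1, a mean FPKM of at least 10 in the higher group, no overlap between the libraries of the groups compared (left out for the interactions) and a standard name. They were taken from the 12 highest and 12 lowest for WT against 0 h, the 5 highest and 5 lowest for mutants against WT, the 2 highest and 2 lowest for interactions, and the 3 highest and 3 lowest for set2Δ against H3K36A. From each list described, the 2 highest and 2 lowest members qualified by fold change alone. The edited genes were named in every sample. Members of the mating lists in counts, the histone H4 genes, HMRA1, HMLALPHA1 and HMLALPHA2 were singled out after their values were seen. Genes of near-identical families are described as uncertain in places, but not at every mention.

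The median total count was 7055346.5. Counts of replicate libraries varied more than by sampling alone, with a chi-square per degree of freedom from 2.72 (rph1Δ at 3 h) to 14.9 (set2Δ at 0 h) over genes with at least 20 counts. The calls were tested on simulated data with the library sizes and the fitted trend of spread with expression level. That spread was the same in all groups, so the larger replicate spread of set2Δ at 0 h was not modelled. For set2Δ against WT at 0 h, 70 of 100 genes changed by 0.5 log2 and 88 of 100 changed by 1 were called, with 4.24% of calls false. For the 3 h interaction of set2Δ these were 37 and 88, with 2.34% false, so a missed call does not show that a gene was unchanged. Of 40 simulated lists of 30 genes, the 1 list moved by 0.5 was called and 0 others were. The simulated genes varied independently of each other, so false calls of lists whose genes vary together were not tested.

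The alternatives were limma-trend on log2(FPKM + 1) and with pseudocounts of 0.1 and 5, DESeq2 (1.42.0), median-of-ratios scaling, quantile normalization, no low-value filter, a mean FPKM of at least 10, only the groups compared, a replicate term, and each library left out in turn. Library totals without TMM were added after the data were seen. Every other per-gene column of the table was annotation.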

Results

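RNA sequencing measured transcript levels in budding yeast (Saccharomyces cerevisiae, strain CEN.PK) of 4 genotypes. WT cells were set beside rph1Δ cells, which lack the H3K36 demethylase Rph1, set2Δ cells, which lack the H3K36 methyltransferase Set2, and H3K36A cells, whose labels name K36A in both histone H3 genes, HHT1 and HHT2. Cells grew to log phase in rich medium (YPL, 0 h) and were then washed and moved to minimal medium (SL) for 1 h or 3 h. The 12 groups held 2 libraries each. The total count per library ranged from 6623458 to 7677684, with a median of 7055346.5. On the leading principal component of the log2 CPM (counts scaled by library size), which held 63% of the variance, the 8 libraries of 0 h lay between -77.36 and -65.95 and the 16 later libraries between 16.78 and 54.21. Values given after a gene are log2 fold changes ± SE between groups of 2 libraries, levels are mean CPM ± SD of 2 libraries, and a p after a gene group is the adjusted p of its camera test. Words such as rose, higher or fell are used of genes past an adjusted p of 0.05, and they are relative to the TMM-scaled libraries. The highest and lowest genes of a comparison are those among called, named genes with a mean FPKM of at least 10 in the higher group and, outside interactions, no overlap between the libraries compared.

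The edited genes gave the background for every comparison. RPH1 (YER169W, chromosome V, 523369 to 525759 of build sacCer3) held 8 counts over the 6 rph1Δ libraries and 3336 over the 6 WT libraries. SET2 (YJL168C, chromosome X, 102227 to 104428), which overlaps YJL169W, held 0 counts over the 6 set2Δ libraries, where a count of 0 allows up to 3, and 1641 over the WT libraries. In the 6 H3K36A libraries, HHT1 (YBR010W, chromosome II, 256331 to 256741) and HHT2 (YNL031C, chromosome XIV, 575640 to 576050) held 5 and 2 counts, against 16771 and 23721 in WT. The histone H4 genes HHF1 and HHF2 held 4 and 4 counts there, against 29817 and 14348 in WT. How the altered H3 and the H4 of that strain were encoded is not given in the sources used here, so these 4 genes were left without a fold change. These are sums of raw counts without a test.

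The rph1Δ libraries also differed from all others in mating type genes, which set the identity of haploid yeast. The a-factor gene MFA1 held 1 to 19 counts in the 6 rph1Δ libraries and 95 to 329 in the WT libraries, and STE2, the receptor of a cells for alpha-factor, held 50 to 167 against 271 to 1745. The alpha-factor gene MF(ALPHA)1 (YPL187W, chromosome XVI, 193648 to 194145) held 1278 to 22771 counts in rph1Δ and 6 to 19 in WT. STE3, the receptor of alpha cells for a-factor, held 198 to 3705 counts against 44 to 64. In set2Δ and H3K36A it held 3 to 14 and 3 to 11 counts, below WT. It overlaps the open reading frame YKL177W, and the strand of the reads is not given in the sources used here. HMRA1 (YCR097W, chromosome III, 293835 to 294321), whose sequence is repeated at the MAT locus of a cells, held 0 counts in each of the 6 rph1Δ libraries and 31 to 118 in each of the 18 other libraries. At 0 h, 7 of 7 a-specific genes were lower (adjusted p = 3.2e-62). Of the 4 alpha-specific genes, 4 were higher (adjusted p = 2.01e-98). Among the 15 haploid-specific and pheromone genes, 7 were higher (adjusted p = 8e-12), with FUS1 (2.10 ± 0.19) and AGA1 (2.10 ± 0.18) the highest. The levels of MFA1, STE2, MF(ALPHA)1, STE3 and HMRA1 lay apart from WT in each of the 6 rph1Δ libraries, beside every other difference given for rph1Δ. Not all other members stayed apart after 0 h. MF(ALPHA)2 held 8 and 3 counts in rph1Δ at 1 h (WT 1 and 2) and 4 and 5 at 3 h (WT 6 and 3), STE6 stood at -0.02 ± 0.17 at 1 h (adjusted p = 0.959) and -0.07 ± 0.18 at 3 h (adjusted p = 0.829), and SAG1 was lower at 1 h, -0.39 ± 0.12, and not called at 3 h (0.09 ± 0.14, adjusted p = 0.689). Over all times MF(ALPHA)2 held 9 to 22 counts in the set2Δ libraries and 6 to 20 in the H3K36A libraries.

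**Figure D1:**
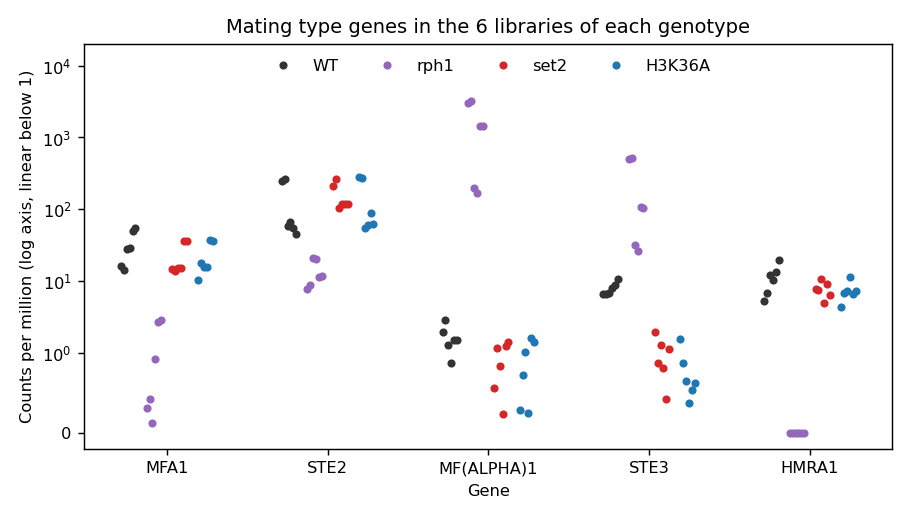
Levels, in CPM, of MFA1, STE2, MF(ALPHA)1, STE3 and HMRA1 in the 6 libraries of each genotype, 1 point per library, on an axis that is logarithmic above 1 and linear below. The rph1Δ points of HMRA1 all lie at 0 counts, and those of MF(ALPHA)1, at 1278 to 22771 counts, lie above all WT points, at 6 to 19 counts.

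The first comparison asked how WT cells responded to minimal medium after 1 h. Genes of sulfur assimilation and methionine synthesis rose steeply: 30 of 32 sulfur and methionine genes rose and 2 fell (adjusted p = 2.89e-20). The ATP sulfurylase gene MET3 (YJR010W, chromosome X, 456239 to 457774) went from 44.2 ± 2.65 to 5710 ± 172 CPM, and STR3 (6.35 ± 0.10), MET10 (6.26 ± 0.10) and BDS1 (6.19 ± 0.17) rose with it. Of the 41 general stress response genes, 36 rose and 1 fell (adjusted p = 2.04e-19), led by the hydrophilin gene GRE1 (YPL223C, chromosome XVI, 128632 to 129138), from 17.4 ± 2.65 to 11110 ± 177 CPM, and by the catalase gene CTT1 (6.33 ± 0.15). Of all 17 fatty acid oxidation and peroxisome genes, 16 rose (adjusted p = 8.42e-12). Among the 32 autophagy genes, 31 rose and 1 fell (adjusted p = 1.01e-08). Members of these groups included FOX2 (3.67 ± 0.09), ATG34 (2.98 ± 0.09) and PRB1 (2.88 ± 0.10). The stationary-phase genes SPG1 (8.25 ± 0.18) and SPG4 (7.06 ± 0.14), the pyruvate decarboxylase isozyme gene PDC6 (7.09 ± 0.14) and the amino acid permease gene AGP3 (6.28 ± 0.13) were also among the 12 with the highest changes.

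Genes for making ribosomes and proteins fell at 1 h in WT. Of the 138 ribosomal protein genes, 137 fell and 1 rose (adjusted p = 2.65e-56). Among the 68 ribosome biogenesis genes, 68 fell (adjusted p = 3.11e-33). Of the 23 translation factor genes, 23 fell (adjusted p = 2.94e-13). NOP1, which encodes the rRNA methyltransferase fibrillarin, fell from 635 ± 16 to 4.98 ± 0.834 CPM, and RPA49 (-6.68 ± 0.17), RPL3 (-6.45 ± 0.12) and YEF3 (-6.89 ± 0.12) fell as well, RPA49 being a subunit of RNA polymerase I and YEF3 an elongation factor. NSR1, a nucleolar protein gene that overlaps YGR160W, changed by -9.42 ± 0.17. The copper transporter gene CTR1, which overlaps YPR123C, and the reductase gene FRE7 changed by -7.03 ± 0.30 and -7.33 ± 0.41. Of nuclear genes for respiration, 32 of 35 respiratory chain genes fell (adjusted p = 1.27e-07, but adjusted p = 0.179 with an estimated correlation), with CYC1 (-3.62 ± 0.10), a cytochrome c gene, the lowest. Of all 20 lactate use and gluconeogenesis genes, 16 rose and 2 fell (adjusted p = 6.5e-05, but adjusted p = 0.349 with an estimated correlation). Among the 21 heat shock chaperone genes, 16 rose and 4 fell (adjusted p = 8.08e-05, but adjusted p = 0.344 with an estimated correlation). Of the 35 proteasome genes, 29 rose and 2 fell (adjusted p = 0.00227, but adjusted p = 0.192 with an estimated correlation). The 26 phospholipid synthesis genes, the pathway named in the study's title, did not move as a group (11 rose and 11 fell, adjusted p = 0.912). In the edgeR test 2425 genes rose and 2262 fell of 6503, 1155 and 1320 of them at least 2-fold, while median-of-ratios scaling gave 2322 higher and 2326 lower.

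After 3 h in minimal medium the WT stress program was still high. Among the 41 general stress response genes, 39 rose and 1 fell (adjusted p = 2.13e-25). Of the 21 heat shock chaperone genes, 17 rose and 4 fell (adjusted p = 7.21e-09, but adjusted p = 0.102 with an estimated correlation). Members of these groups included GRE1 (10.03 ± 0.12), SSA3 (6.86 ± 0.11), HSP26 (6.40 ± 0.12) and CTT1 (6.26 ± 0.15), where SSA3 and HSP26 encode chaperones. Of all 32 sulfur and methionine genes, 26 rose and 4 fell (adjusted p = 9.67e-12). Among the 32 autophagy genes, 30 rose (adjusted p = 4.56e-09). Of the 17 fatty acid oxidation and peroxisome genes, 15 rose (adjusted p = 5.88e-08). Among the 35 proteasome genes, 32 rose (adjusted p = 1.8e-07). The formate dehydrogenase gene FDH1 (YOR388C, chromosome XV, 1071793 to 1072923) went from 14.0 ± 1.16 to 2213 ± 246 CPM. On the other side, 136 of 138 ribosomal protein genes fell and 1 rose (adjusted p = 2.03e-37, but adjusted p = 0.0715 with an estimated correlation). Of the 68 ribosome biogenesis genes, 67 fell (adjusted p = 9.88e-19). Of all 23 translation factor genes, 21 fell and 1 rose (adjusted p = 4.85e-08, but adjusted p = 0.0508 with an estimated correlation). Respiratory chain genes stayed lower (31 of 35 fell, adjusted p = 1.89e-08, but adjusted p = 0.133 with an estimated correlation). The peptide and amino acid permease genes PTR2 (-6.15 ± 0.14), TAT1 (-5.24 ± 0.13) and BAP3 (-5.17 ± 0.18) and the copper uptake genes CTR3 (-5.38 ± 0.23) and FRE1 (-4.67 ± 0.27) were among the 12 lowest. BSC1 held 155 counts over the 2 libraries of 0 h and 3 at 3 h. Among the 24 G1 and S phase genes, 16 fell and 2 rose (adjusted p = 0.0011, but adjusted p = 0.162 with an estimated correlation). Phospholipid synthesis genes again went both ways (8 rose and 12 fell, adjusted p = 0.701). By edgeR 2314 genes rose and 2211 fell, 1096 and 1135 of them at least 2-fold, but 1914 higher and 2577 lower with library totals, 1929 higher and 2593 lower by limma-trend, 2144 higher and 2373 lower with median-of-ratios scaling and 2108 higher and 2334 lower by DESeq2.

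Between 1 h and 3 h the WT cells turned part of this response around. Of the 138 ribosomal protein genes, 135 rose, or 136 adjusted over the list alone (adjusted p = 3.01e-87). Among the 68 ribosome biogenesis genes, 68 rose (adjusted p = 3.42e-49). Of the 23 translation factor genes, 23 rose (adjusted p = 2.27e-14). SUI2, the smallest of the last, stood at -0.09 with library totals. The largest of these changes were in NSR1, at 6.85 ± 0.19, and RPA49 (4.72 ± 0.19) and YEF3 (4.39 ± 0.11). Of all 32 sulfur and methionine genes, 29 fell and 2 rose (adjusted p = 1.53e-35), with the methionine permease gene MUP1 (-3.30 ± 0.10) and the cystathionine gamma-lyase gene CYS3 (-2.99 ± 0.09) the lowest. Among the 17 fatty acid oxidation and peroxisome genes, 15 fell (adjusted p = 2.27e-14). Of the 25 ergosterol synthesis genes, 20 rose, or 20 with 1 falling adjusted over the list alone (adjusted p = 7.98e-06). Among the 25 pyrimidine metabolism genes, 17 rose and 1 fell, or 19 and 1 adjusted over the list alone (adjusted p = 4.28e-05). Of the 25 glycolysis and hexose transport genes, 20 rose and 1 fell (adjusted p = 2.55e-10, but adjusted p = 0.0984 with an estimated correlation), with PDC1 (3.75 ± 0.10) and CDC19 (2.87 ± 0.10), which encode pyruvate decarboxylase and pyruvate kinase, the highest. By edgeR 1781 genes rose and 1214 fell. The split leaned on the scaling, since it was 1010 higher and 2623 lower with library totals and 1283 higher and 1761 lower after quantile normalization, while the directions of these lists held under each scaling.

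**Figure D2:**
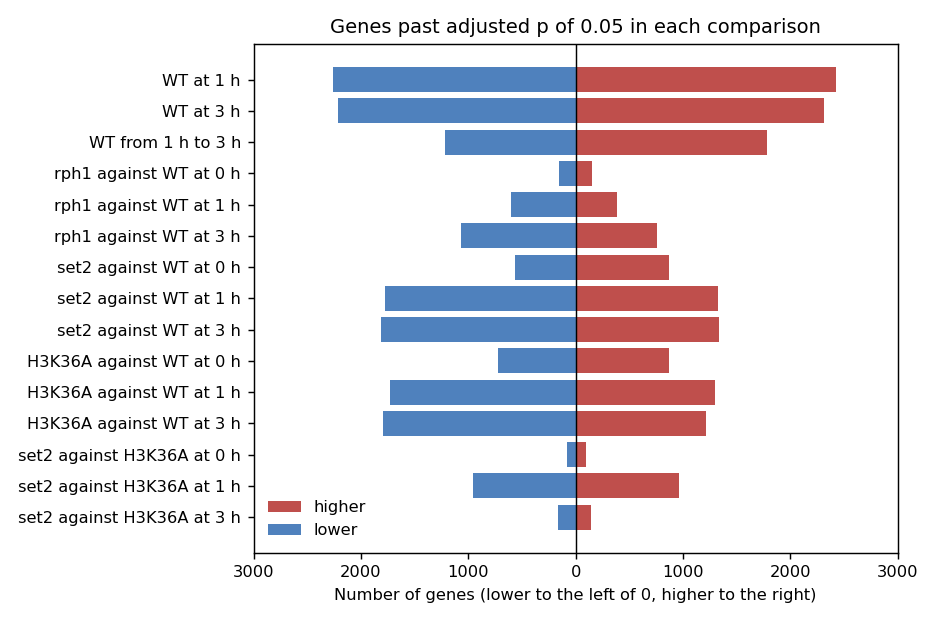
Number of genes past an adjusted p of 0.05 in each comparison (edgeR, groups of 2 libraries), with genes lower in the group named first drawn to the left of 0 and genes higher to the right. WT at 1 h has the longest bars (2425 and 2262 genes) and rph1Δ against WT at 0 h has 157 genes on either side. With library totals in place of TMM, WT from 1 h to 3 h went to 1010 higher and 2623 lower.

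The next comparisons set rph1Δ cells, which lack the demethylase Rph1, beside WT. HMRA1 gave 0 counts in every rph1Δ library. An effect of Rph1 loss therefore cannot be told apart from one of mating type in any of these comparisons. In rich medium the main group outside mating was glycolysis, where 18 of 25 glycolysis and hexose transport genes were lower and 1 higher (adjusted p = 1.64e-53), among them the enolase and glyceraldehyde-phosphate dehydrogenase genes ENO1 (-1.78 ± 0.11) and TDH2 (-1.57 ± 0.11), whose near-identical paralogs leave the share of each copy uncertain. Of all 18 phosphate starvation genes, 8 were lower, or 10 adjusted over the list alone (adjusted p = 1.69e-18), with SPL2 (-2.04 ± 0.31) and PHO84 (-1.89 ± 0.13) the lowest, PHO84 being the high-affinity phosphate transporter gene. Among the 68 ribosome biogenesis genes, 15 were lower, or 41 adjusted over the list alone (adjusted p = 5.07e-21). Of the 20 lactate use and gluconeogenesis genes, 11 were higher, or 16 adjusted over the list alone (adjusted p = 2.77e-15), with the transcription factor gene SIP4 (0.88 ± 0.10) the highest. Among the 32 autophagy genes, 3 were higher, or 6 adjusted over the list alone (adjusted p = 0.00129), with a median of 0.15. The 26 phospholipid synthesis genes did not move as a group (adjusted p = 0.367). By edgeR 157 genes were higher and 157 lower, 16 and 37 at least 2-fold, in libraries with 0 HMRA1 counts. The count fell to 155 without WT 0 h replicate 1, 161 without rph1Δ 0 h replicate 1 and 194 without rph1Δ 0 h replicate 2. It was 499 when only the groups compared were fitted, and library totals gave 246 higher and 119 lower.

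At 1 h in minimal medium, rph1Δ cells had lower levels of mitochondrial energy genes than WT. Of the 35 respiratory chain genes, 31 were lower, or 32 adjusted over the list alone (adjusted p = 4.57e-39). Of all 25 TCA cycle genes, 19 were lower and 1 higher, or 19 and 2 adjusted over the list alone (adjusted p = 1.24e-34), with the fumarase gene FUM1 (YPL262W, chromosome XVI, 47336 to 48802) at 759 ± 13.4 CPM against 2056 ± 113 in WT, and IDH1 (-1.31 ± 0.08), NDE1 (-1.19 ± 0.07) and COX6 (-1.08 ± 0.10). Among the 20 lactate use and gluconeogenesis genes, 13 were lower, or 14 adjusted over the list alone (adjusted p = 2.94e-16). Of the 25 glycolysis and hexose transport genes, 15 were lower, or 15 with 1 higher adjusted over the list alone (adjusted p = 1.32e-14). Among the 20 purine synthesis genes, 13 were lower and 1 higher, or 16 and 1 adjusted over the list alone (adjusted p = 1.51e-10), with the glycine and serine enzyme genes SHM2 (-1.16 ± 0.11) and GCV2 (-0.86 ± 0.10). Of the 21 heat shock chaperone genes, 16 were higher, or 18 adjusted over the list alone (adjusted p = 2.07e-15), with BTN2 (1.04 ± 0.09) and SSA4 (0.75 ± 0.09) the highest. Of all 11 branched chain amino acid synthesis genes, 5 were higher, or 6 with 1 lower adjusted over the list alone (adjusted p = 1.81e-08), with ILV2 (0.99 ± 0.08) and BAT1 (0.98 ± 0.08). The repressor gene ROX1 (1.21 ± 0.19) and the branched-chain amino acid permease gene BAP2 (1.19 ± 0.11) were among the 5 highest. In these libraries 6 of 7 a-specific genes were lower (adjusted p = 3.2e-21), and MF(ALPHA)1 stood at 7.36 ± 0.19. By edgeR 384 genes were higher and 603 lower, but 924 higher and 384 lower with library totals. The count was 504 without WT 1 h replicate 1, 619 without WT 1 h replicate 2 and 507 without rph1Δ 1 h replicate 1.

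At 3 h the largest group in rph1Δ was ribosomal: 110 of 138 ribosomal protein genes were lower, or 119 with 1 higher adjusted over the list alone (adjusted p = 3.36e-25, but adjusted p = 0.272 with an estimated correlation), with a median of -0.41 and RPS12 (-0.77 ± 0.10) among the lowest. In the same libraries 6 of 7 a-specific genes were lower (adjusted p = 2.64e-20). Among the 4 alpha-specific genes, 2 were higher (adjusted p = 5.89e-14), STE3 at 3.42 ± 0.15. The agglutinin gene AGA1 (1.41 ± 0.21) and COS12 (1.38 ± 0.21) were among the 5 highest. Of the 11 histone genes, 8 were lower, or 9 adjusted over the list alone (adjusted p = 7.95e-05, but adjusted p = 0.349 with an estimated correlation). The phosphatidylethanolamine methyltransferase gene CHO2 (-0.63 ± 0.09) and the phosphatidylserine synthase gene CHO1 (-0.49 ± 0.08) were lower, while of the whole list 9 of 26 phospholipid synthesis genes were lower and 2 higher, or 13 and 3 adjusted over the list alone (adjusted p = 0.0489, but adjusted p = 0.21 with an estimated correlation). That call ended with library totals (adjusted p = 0.16), median-of-ratios scaling (adjusted p = 0.0637) or quantile normalization (adjusted p = 0.0541), and without WT 3 h replicate 1 (adjusted p = 0.255), rph1Δ 3 h replicate 1 (adjusted p = 0.0737) or rph1Δ 3 h replicate 2 (adjusted p = 0.0607). By edgeR 754 genes were higher and 1066 lower, but 1410 higher and 497 lower with library totals and 614 higher and 452 lower after quantile normalization. The count was 548 without WT 3 h replicate 2, 922 without rph1Δ 3 h replicate 1 and 1113 without rph1Δ 3 h replicate 2, and 1052 when only the groups compared were fitted.

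Cells without the methyltransferase Set2 had higher stress gene levels already in rich medium. Among the 41 general stress response genes, 34 were higher (adjusted p = 5.27e-25). Of the 21 heat shock chaperone genes, 17 were higher (adjusted p = 3.82e-22). Members of these groups included TSL1 (1.28 ± 0.12), HSP30 (1.49 ± 0.17), HSP42 (1.25 ± 0.10) and BTN2 (1.31 ± 0.11). The polygalacturonase gene PGU1 (YJR153W, chromosome X, 722815 to 723900) had the highest change of genes with a mean FPKM of at least 10, 3.62 ± 0.36, and the putative aryl-alcohol dehydrogenase genes AAD16 (3.43 ± 0.20) and AAD6 (3.04 ± 0.13) and the vitamin B6 gene SNO1 (2.76 ± 0.30) were among the 5 highest. Some genes are known for promoters inside their coding sequence, and 5 of 8 such cryptic promoter genes were higher (adjusted p = 0.00285, but adjusted p = 0.0508 with an estimated correlation), PCA1 with the highest value at 1.20 ± 0.11. Counts per gene do not show where transcripts began, so use of such promoters was not measured here or in any later comparison. Of all 18 arginine and lysine synthesis genes, 8 were higher (adjusted p = 8.27e-05, but adjusted p = 0.0508 with an estimated correlation), with ARG3 (1.36 ± 0.15) and ARG1 (1.34 ± 0.07). Among the 25 iron regulon genes, 10 were higher, or 11 adjusted over the list alone (adjusted p = 0.00078, but adjusted p = 0.293 with an estimated correlation), with the siderophore binding gene FIT3 (1.71 ± 0.15). Of the 68 ribosome biogenesis genes, 29 were lower, or 34 adjusted over the list alone (adjusted p = 7.59e-12, but adjusted p = 0.106 with an estimated correlation). The inositol phosphate synthase gene INO1 (YJL153C, chromosome X, 134332 to 135933), at 90.5 ± 5.49 CPM against 306 ± 45.6, and IZH4 (-1.98 ± 0.28) and ICY1 (-1.60 ± 0.17) were among the 5 lowest. By edgeR 867 genes were higher and 568 lower, 232 and 32 at least 2-fold, but 658 higher and 776 lower among genes with a mean FPKM of at least 10. The count was 888 without WT 0 h replicate 1 and 934 without WT 0 h replicate 2, and 656 when only the groups compared were fitted.

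At 1 h in minimal medium, genes for building ribosomes stood higher in set2Δ than in WT. Among the 68 ribosome biogenesis genes, 55 were higher, or 55 with 1 lower adjusted over the list alone (adjusted p = 1.03e-28), with a median of 1.20 (0.65 after quantile normalization). The helicase gene DRS1 (YLL008W, chromosome XII, 131729 to 133987) stood at 254 ± 0.779 CPM against 3.78 ± 0.0345, and NOP4, which overlaps YPL044C, at 3.67 ± 0.17. By contrast, 111 of 138 ribosomal protein genes were lower, or 118 adjusted over the list alone (adjusted p = 2.74e-15, but adjusted p = 0.25 with an estimated correlation). Of the 35 proteasome genes, 34 were lower, or 35 adjusted over the list alone (adjusted p = 1.49e-16), the proteasome assembly gene UMP1 (-0.92 ± 0.07) being the lowest. Of all 25 glycolysis and hexose transport genes, 19 were lower, or 19 with 1 higher adjusted over the list alone (adjusted p = 3.56e-15, but adjusted p = 0.0564 with an estimated correlation), among them ENO2 (-2.57 ± 0.11) and TDH1 (-2.49 ± 0.16). Among the 17 fatty acid oxidation and peroxisome genes, 15 were lower and 1 higher (adjusted p = 2.76e-11), with IDP3 (-1.45 ± 0.08) and SPS19 (-1.20 ± 0.10). Of the 8 cryptic promoter genes, 8 were higher (adjusted p = 1.51e-05), with AVO1 (1.35 ± 0.13) and SPB4 (1.24 ± 0.11) the highest. AZR1, a plasma membrane transporter gene, held 3 counts over the 2 WT libraries and 275 over the 2 set2Δ libraries, and the formate dehydrogenase gene FDH1 (-3.12 ± 0.13) and the acetate transporter gene ADY2 (-2.64 ± 0.11) were among the 5 lowest. By edgeR 1329 genes were higher and 1777 lower, 455 and 173 at least 2-fold, but 2194 higher and 906 lower with library totals.

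At 3 h, set2Δ cells had higher levels of cell cycle genes than WT. Among the 24 G1 and S phase genes, 18 were higher and 1 lower (adjusted p = 1.69e-08), with HO (1.86 ± 0.18) and CLN1 (1.72 ± 0.17) the highest, CLN1 being a G1 cyclin gene. Of the 22 G2 and M phase genes, 14 were higher and 1 lower (adjusted p = 1.82e-06, but adjusted p = 0.184 with an estimated correlation), with BUD4 (1.48 ± 0.12) and CLB2 (1.27 ± 0.18). Of all 25 glycolysis and hexose transport genes, 21 were lower (adjusted p = 2.9e-13, but adjusted p = 0.0718 with an estimated correlation), with TDH1 (-3.22 ± 0.15) the lowest. Among the 35 proteasome genes, 27 were lower, or 28 adjusted over the list alone (adjusted p = 7.15e-07, but adjusted p = 0.052 with an estimated correlation). Of the 26 phospholipid synthesis genes, 12 were lower and 2 higher, or 13 and 2 adjusted over the list alone (adjusted p = 0.00308), and its lowest members were INO1 (-2.24 ± 0.10) and OPI3 (-1.16 ± 0.10), OPI3 being the phospholipid methyltransferase gene of phosphatidylcholine synthesis. Among the 26 vitamin genes, 14 were lower and 4 higher (adjusted p = 0.00308, but adjusted p = 0.124 with an estimated correlation), with THI13 (-2.75 ± 0.28) and THI11 (-2.53 ± 0.24), members of a near-identical family whose copies reads cannot fully tell apart, the lowest. Of the 8 cryptic promoter genes, 8 were higher (adjusted p = 1.96e-05). Of all 10 flocculation and filamentation genes, 8 were higher (adjusted p = 9.57e-07, but adjusted p = 0.0889 with an estimated correlation), with FLO1 (2.95 ± 0.42), a subtelomeric flocculin gene. JIP3, which overlaps MID2, held 1 count over the 2 WT libraries and 72 over the 2 set2Δ libraries. By edgeR 1337 genes were higher and 1811 lower, 325 and 196 at least 2-fold, but 2323 higher and 783 lower with library totals.

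The H3K36A strain approached the same question through the histone itself. Its libraries held only 5, 2, 4 and 4 counts of HHT1, HHT2, HHF1 and HHF2. Each comparison with WT therefore holds that difference in H3 and H4 genes beside the K36A named in the labels. In rich medium 31 of 41 general stress response genes were higher and 1 lower (adjusted p = 9.43e-30). Among the 21 heat shock chaperone genes, 16 were higher (adjusted p = 1.49e-19). Members of these groups included TSL1 (1.75 ± 0.12), GRE1 (1.64 ± 0.12) and HSP42 (1.41 ± 0.10). With a mean FPKM of at least 10, the 5 highest genes were PGU1 (4.05 ± 0.35), HPF1 (3.09 ± 0.15), AAD6 (3.06 ± 0.13), AAD16 (2.99 ± 0.20) and SNO1 (2.36 ± 0.31). Of the 18 arginine and lysine synthesis genes, 9 were higher, or 10 adjusted over the list alone (adjusted p = 4.86e-05), with ARG3 (1.24 ± 0.15). Among the 8 cryptic promoter genes, 5 were higher (adjusted p = 0.00151), with PCA1 (1.27 ± 0.11) and STE11 (0.89 ± 0.09). Of the 68 ribosome biogenesis genes, 53 were lower, or 61 adjusted over the list alone (adjusted p = 6.78e-22), with a median of -0.42. Of all 25 glycolysis and hexose transport genes, 18 were lower and 2 higher (adjusted p = 3.31e-12, but adjusted p = 0.0593 with an estimated correlation), with TDH2 (-1.42 ± 0.11) and CDC19 (-1.34 ± 0.10). Outside HHT1, HHT2, HHF1 and HHF2, the arsenate reductase gene ARR2 (-2.10 ± 0.47) was the lowest named. By edgeR 870 genes were higher and 722 lower, 204 and 45 at least 2-fold, with 1094 higher and 481 lower under library totals but 703 higher and 867 lower among genes with a mean FPKM of at least 10. The count was 1022 without WT 0 h replicate 1.

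At 1 h, H3K36A cells also held more ribosome biogenesis transcripts than WT: 42 of 68 ribosome biogenesis genes were higher and 4 lower, or 44 and 6 adjusted over the list alone (adjusted p = 1.79e-17), with a median of 0.84 (0.44 after quantile normalization), DRS1 (5.69 ± 0.19) and, among the lower members, NOP58 (-1.27 ± 0.26). NOP4, which overlaps YPL044C, stood at 4.43 ± 0.17. Among the 138 ribosomal protein genes, 121 were lower and 1 higher, or 126 and 1 adjusted over the list alone (adjusted p = 1.17e-24, but adjusted p = 0.142 with an estimated correlation). Energy and sterol genes were lower: 17 of 25 glycolysis and hexose transport genes were lower and 3 higher (adjusted p = 9.67e-16). Of the 35 respiratory chain genes, 31 were lower, or 32 adjusted over the list alone (adjusted p = 3.67e-09, but adjusted p = 0.11 with an estimated correlation). Among the 25 TCA cycle genes, 17 were lower and 1 higher (adjusted p = 1.18e-06). Of the 25 ergosterol synthesis genes, 20 were lower and 2 higher, or 21 and 2 adjusted over the list alone (adjusted p = 1.63e-08). Members of these groups included ENO2 (-3.95 ± 0.12), GPM1 (-3.65 ± 0.13), CIT2 (-1.69 ± 0.09) and ERG25 (-1.78 ± 0.07). Of all 8 cryptic promoter genes, 8 were higher (adjusted p = 1.36e-06). The hexose transporter gene HXT14, which overlaps YNL319W, and VBA5 (4.58 ± 0.37) were among the 5 highest, HXT14 at 5.83 ± 0.23, and PDC6 (-4.46 ± 0.11) was the lowest outside the histone genes. By edgeR 1299 genes were higher and 1734 lower, 443 and 232 at least 2-fold, but 1994 higher and 1057 lower with library totals. Quantile normalization ended the call of the TCA cycle list (adjusted p = 0.083).

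**Figure D3:**
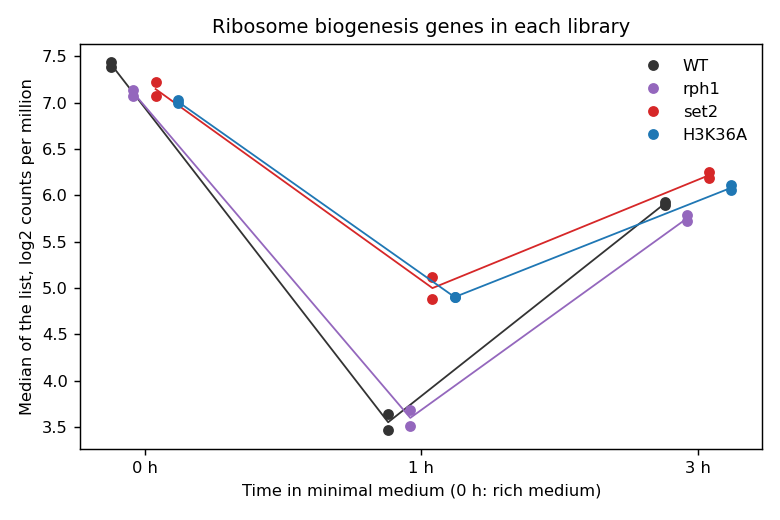
Median log2 CPM of the 68 ribosome biogenesis genes in each library (points) against time, with lines through the mean of the 2 libraries of each group. At 1 h the WT libraries lie at 3.64 and 3.46 and the rph1Δ libraries at 3.69 and 3.51, below the set2Δ libraries, at 5.11 and 4.88, and the H3K36A libraries, at 4.90 and 4.90.

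At 3 h, 17 of 22 G2 and M phase genes were higher and 1 lower (adjusted p = 1.21e-08, but adjusted p = 0.171 with an estimated correlation). Among the 24 G1 and S phase genes, 15 were higher and 1 lower, or 16 and 1 adjusted over the list alone (adjusted p = 4.8e-07, but adjusted p = 0.0591 with an estimated correlation), with the bud site selection gene BUD4 (1.62 ± 0.12) and CLN1 (1.40 ± 0.17) the highest of these lists. Of the 8 cryptic promoter genes, 8 were higher (adjusted p = 2.55e-06), FLO8 (1.25 ± 0.21) and DDC1 (1.10 ± 0.13) being the highest. Among the 25 glycolysis and hexose transport genes, 17 were lower and 1 higher (adjusted p = 1.22e-11, but adjusted p = 0.108 with an estimated correlation), with TDH1 (-2.45 ± 0.14) the lowest. Of the 35 proteasome genes, 30 were lower, or 32 adjusted over the list alone (adjusted p = 1.21e-08), a call that quantile normalization ended (adjusted p = 0.0725). The sporulation-induced gene SPS4 (2.60 ± 0.27) and DRS1 (2.62 ± 0.14) were among the 5 highest. Among phospholipid synthesis genes, levels were lower in 11 and higher in 1 of 26 cases, and the list did not pass (adjusted p = 0.0852). By edgeR 1215 genes were higher and 1793 lower, 294 and 152 at least 2-fold, but 2210 higher and 736 lower with library totals and 1230 higher and 1068 lower after quantile normalization.

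Whether the response to minimal medium differed between genotypes was tested as an interaction, the mutant's change from 0 h less that of WT, and higher or lower refer here to that difference. In set2Δ at 1 h the response of ribosome biogenesis genes was higher in 56 of 68 cases (60 adjusted over the list alone, adjusted p = 2.3e-59), and in H3K36A 50 of 68 ribosome biogenesis genes were higher and 1 lower, or 55 and 1 adjusted over the list alone (adjusted p = 3.93e-49). The library medians of this list lay below those of WT at 0 h in both mutants, which adds to these interactions. The rise of stress genes was smaller in both mutants, since at 1 h 38 of 41 general stress response genes were lower (adjusted p = 3.08e-27) in set2Δ and 35 of 41 general stress response genes were lower, or 36 adjusted over the list alone (adjusted p = 7.42e-20) in H3K36A. At 3 h 37 of 41 general stress response genes were lower, or 38 adjusted over the list alone (adjusted p = 1.43e-34) and 20 of 21 heat shock chaperone genes were lower (adjusted p = 3.18e-24) in set2Δ, and 36 of 41 general stress response genes were lower and 1 higher, or 37 and 1 adjusted over the list alone (adjusted p = 1.8e-37) and 20 of 21 heat shock chaperone genes were lower (adjusted p = 1.19e-26) in H3K36A; these lists already stood higher at 0 h in both. The hexokinase gene HXK1 (-2.55 ± 0.15) and the stress-induced membrane protein gene HSP30 (-3.41 ± 0.23) had the lowest interactions of the stress list in set2Δ. By edgeR 1827 genes responded differently in set2Δ at 1 h (711 higher and 1116 lower) and 2123 at 3 h (883 and 1240), and in H3K36A 1812 (644 and 1168) and 1771 (692 and 1079). Library totals moved these splits to 1196 higher and 612 lower, 1589 higher and 654 lower, 848 higher and 759 lower, and 1148 higher and 561 lower, and median-of-ratios scaling to 914 higher and 824 lower, 1043 higher and 1013 lower, 786 higher and 832 lower, and 854 higher and 817 lower.

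In rph1Δ, where RPH1 loss cannot be separated from mating type, the 1 h response of energy genes was lower than in WT. Of all 25 TCA cycle genes, 19 were lower, or 19 with 1 higher adjusted over the list alone (adjusted p = 3.69e-34), with CIT2 (-2.17 ± 0.13) and FUM1 (-1.49 ± 0.11). Among the 35 respiratory chain genes, 23 were lower, or 30 with 1 higher adjusted over the list alone (adjusted p = 1.35e-25). Of the 20 lactate use and gluconeogenesis genes, 16 were lower, or 20 adjusted over the list alone (adjusted p = 2.82e-33), with YAT2 (-1.54 ± 0.12) and SFC1 (-1.53 ± 0.12). Among the 18 phosphate starvation genes, 8 were higher, or 10 adjusted over the list alone (adjusted p = 2.51e-12), with SPL2 (2.33 ± 0.44) and PHO89 (1.32 ± 0.10) the highest. Mating genes responded differently too: at 1 h 4 of 4 alpha-specific genes were lower (adjusted p = 1.7e-16) and at 3 h 4 of 7 a-specific genes were higher (adjusted p = 5.88e-10). At 3 h 5 of 26 phospholipid synthesis genes were lower, or 10 with 2 higher adjusted over the list alone (adjusted p = 0.00549), with CHO2 (-0.82 ± 0.12) the lowest; without WT 3 h replicate 1 this call ended (adjusted p = 0.0556). By edgeR 554 genes responded differently at 1 h (214 higher and 340 lower) and 440 at 3 h (196 and 244, but 269 higher and 146 lower with library totals). The 1 h count was 328 without rph1Δ 0 h replicate 1 and 341 without rph1Δ 1 h replicate 1, and 884 when only the groups compared were fitted. The 3 h count was 242 without WT 0 h replicate 1, 152 without WT 0 h replicate 2, 119 without rph1Δ 0 h replicate 1, 257 without rph1Δ 0 h replicate 2, 1182 without WT 3 h replicate 1, 142 without WT 3 h replicate 2, 165 without rph1Δ 3 h replicate 1 and 175 without rph1Δ 3 h replicate 2, 256 by limma on log2 FPKM and 243 after quantile normalization.

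Set side by side, set2Δ and H3K36A cells were separated by fewer genes at 0 h and 3 h than at 1 h. At 1 h 33 of 35 respiratory chain genes were higher (adjusted p = 1.74e-30) in set2Δ than in H3K36A. In the same direction, 18 of 25 TCA cycle genes were higher and 3 lower (adjusted p = 1.8e-12). Of the 20 purine synthesis genes, 15 were higher and 2 lower, or 17 and 2 adjusted over the list alone (adjusted p = 2.26e-18). Of all 32 sulfur and methionine genes, 25 were higher and 1 lower, or 28 and 1 adjusted over the list alone (adjusted p = 3.92e-15). Among the 25 ergosterol synthesis genes, 14 were higher and 2 lower, or 15 and 3 adjusted over the list alone (adjusted p = 7.9e-06). Of the 17 fatty acid oxidation and peroxisome genes, 14 were lower and 1 higher, or 15 and 1 adjusted over the list alone (adjusted p = 8.38e-22). Among the 18 arginine and lysine synthesis genes, 9 were higher and 1 lower (adjusted p = 0.000112). Of the 19 histidine and tryptophan synthesis genes, 7 were higher and 1 lower, or 11 and 1 adjusted over the list alone (adjusted p = 6.35e-05). Single genes that stood apart at 1 h were CYC1 (1.50 ± 0.09), SHM2 (1.95 ± 0.11), FDH1 (-4.10 ± 0.14) and ADY2 (-3.15 ± 0.12). At 3 h 7 of 25 TCA cycle genes were higher, or 9 adjusted over the list alone (adjusted p = 1.56e-07). Of all 18 arginine and lysine synthesis genes, 5 were higher, or 7 adjusted over the list alone (adjusted p = 3.63e-05), with ARG1 (0.69 ± 0.07). By edgeR 100 genes were higher and 77 lower in set2Δ at 0 h (79 higher and 97 lower with library totals), 965 and 952 at 1 h (954 higher and 963 lower with median-of-ratios scaling), and 145 and 160 at 3 h (160 higher and 141 lower with library totals), the edited genes among them. The 0 h count of 177 was 302 without set2Δ 0 h replicate 2 and 71 without H3K36A 0 h replicate 1, and 15 when only the groups compared were fitted. The 3 h count of 305 was 139 without set2Δ 3 h replicate 1, 85 without set2Δ 3 h replicate 2, 157 without H3K36A 3 h replicate 1 and 87 without H3K36A 3 h replicate 2, and 735 with only the groups compared.

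Changes shared by set2Δ and H3K36A against WT were counted over the 6497 tested genes outside the edited genes. At 0 h 652 genes were higher in both and 364 lower in both, where independent lists would share 116 and 62.7, and 2 went opposite ways. PGU1, AAD6, AAD16, HPF1 and SNO1 were the 5 highest genes of both strains at that time with a mean FPKM of at least 10. At 1 h the counts were 935 and 1081 (266 and 472 by chance), with 142 opposite, and DRS1 and VBA5 were among the 5 highest of both. At 3 h they were 1002 and 1421 (250 and 498 by chance), with 3 opposite, and DRS1 was among the 5 highest of both. Both mutants were compared with the same 2 WT libraries at each time, which by itself makes their changes covary. The covariance of the log2 changes across genes was 0.611, 0.935 and 0.872 at 0 h, 1 h and 3 h, against 0.0264 simulated at each time for shared WT libraries and no true change, and genes are not independent replicates. The simulation gave a gene the same spread in all groups. The wider replicate spread of WT at 3 h (chi-square per degree of freedom 12.8, against 3.17 at 0 h and 3.04 at 1 h) was not modelled. The 0 h sum of 1016 genes was 619 without WT 0 h replicate 1 and 580 when only the groups compared were fitted, and the 3 h sum of 2423 was 1608 without WT 3 h replicate 2.

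**Figure D4:**
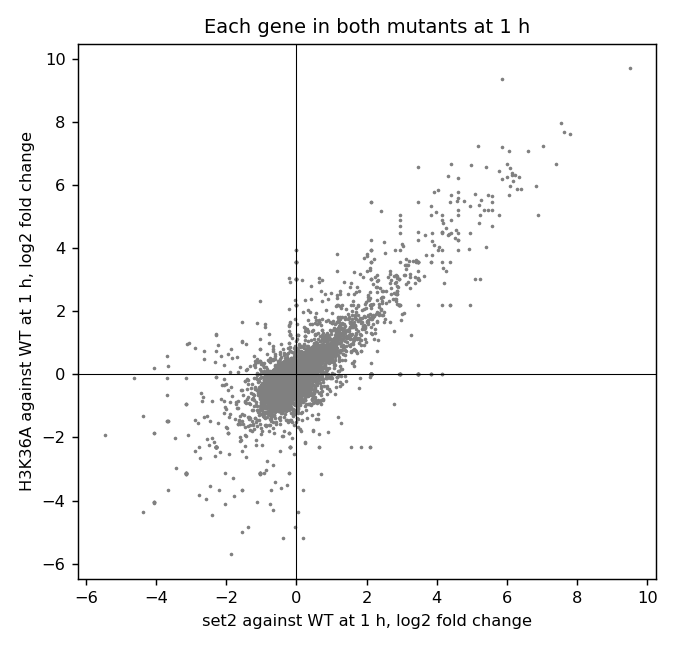
Log2 fold change against WT at 1 h in set2Δ (horizontal axis) and in H3K36A (vertical axis), 1 point for each of 6497 genes, with the edited genes left out. Of the genes called in both strains, 935 were higher in both, 1081 lower in both and 142 opposite, and both axes share the same 2 WT libraries.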

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

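The interactions given for each mutant stood out because its change from 0 h differed from that of WT by a test of the difference itself (edgeR interaction for genes, camera for lists), while the 3 patterns weighed after them rest on direct comparisons with WT. The tests of opposite mating type, mixed cells, library scaling, the course of rph1Δ cells and low WT values as a whole cause were chosen only after the result was seen. No test for a single library far from its replicate and no other split of the libraries was run. The replicate chi-square per degree of freedom was 14.9 in set2Δ at 0 h, 12.8 in WT at 3 h and 2.72 to 9.76 in the other 10 groups. Values for each mutant are log2 interactions, as medians for lists.

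The largest list interactions in rph1Δ were of mating genes. Against WT at 0 h the a-specific list stood at -4.99 and the alpha-specific list at 7.88. Interactions of the opposite sign mean that these gaps narrowed in minimal medium. At 1 h the a-specific list stood at 2.88, the alpha-specific list at -4.01 and the haploid-specific list at -0.18, with MFA2 (3.54 ± 0.80) and STE3 (-4.29 ± 0.26). MFA2 held only 1 and 3 counts in the rph1Δ libraries of 0 h, so the size of its interactions at both times is uncertain. At 3 h the a-specific list stood at 2.58 and the alpha-specific list at -3.04, with MFA2 (3.57 ± 0.75), STE2 (2.84 ± 0.26) and FUS1 (-3.26 ± 0.34) and a fitted value of -9.68 for MF(ALPHA)2, whose WT 0 h libraries held 5 counts together, so that it is no measure of size. MFA2 lost its call at 3 h without rph1Δ 0 h replicate 1 (3.08, adjusted p = 0.0636) and without rph1Δ 3 h replicate 1 (3.12, adjusted p = 0.0781). Other lists of rph1Δ at 1 h were branched chain amino acid synthesis (0.65), TCA cycle (-0.63), respiratory chain (-0.57), lactate use (-0.61), fatty acid oxidation (-0.41) and phosphate starvation (0.71). At 3 h they were phospholipid synthesis (-0.28, not past the threshold without WT 3 h replicate 1, adjusted p = 0.0556) and phosphate starvation (0.48). The numbers of genes were 554 at 1 h and 440 at 3 h, and the second ran from 119 to 1182 as single libraries were left out.

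Ribosome biogenesis and stress genes responded differently in set2Δ. At 1 h the medians were 1.41 for ribosome biogenesis, -0.98 for general stress, -1.06 for heat shock chaperones, -0.92 for fatty acid oxidation and -0.65 for the proteasome. At 3 h they were -1.09 for general stress, -1.03 for heat shock chaperones, -0.41 for the proteasome and 0.73 for G1 and S phase. Single genes were DRS1 (6.55 ± 0.23), NOP4 (3.85 ± 0.22), FDH1 (-3.36 ± 0.25) and HEF3 (-3.13 ± 0.14) at 1 h, where NOP4 overlaps YPL044C and the elongation factor gene HEF3 overlaps YNL013C, and DRS1 (3.39 ± 0.18) and the a-specific gene ASG7 (-3.76 ± 0.41) at 3 h. ASG7 (chromosome X, 101150 to 101779) lies close to the deleted SET2 (102227 to 104428). A local effect of the deletion on it was not tested. The numbers of genes were 1827 and 2123.

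Ribosome biogenesis and stress genes responded differently from WT in H3K36A too. Its 1 h medians were 1.25 for ribosome biogenesis, -0.80 for general stress, -1.25 for heat shock chaperones, -0.41 for the proteasome, -0.42 for the TCA cycle and -0.36 for ergosterol synthesis. At 3 h they were 0.49, -1.04, -0.97 and -0.40 for the first 4 of these. The ribosome biogenesis interactions include a lower 0 h level. The H3K36A library medians of that list were 7.03 and 6.99 log2 CPM at 0 h, against 7.43 and 7.39 in WT. At 3 h they were 6.11 and 6.05, against 5.93 and 5.90 in WT. Single genes were DRS1 (6.26 ± 0.23), NOP4 (4.84 ± 0.21), PDC6 (-4.14 ± 0.26) and AAD6 (-3.21 ± 0.17) at 1 h and the peptide transporter gene OPT2 (3.65 ± 0.46), DRS1 (3.20 ± 0.18) and the seripauperin gene PAU2 (-2.96 ± 0.57), one of a near-identical family, at 3 h. The numbers of genes were 1812 and 1771.

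The mating genes of rph1Δ are the pattern with the largest values. Cells of mixed mating type in the rph1Δ cultures were argued against, since HMRA1 gave 0 counts there and 442 in the 6 WT libraries, an upper limit of 0.679% of the WT level. Against WT at 0 h the medians were -4.99 for the a-specific and 7.88 for the alpha-specific list. The silent-locus genes HMLALPHA1 and HMLALPHA2, whose sequences are repeated at the MAT locus of alpha cells, held 4 and 13 counts over the 6 rph1Δ libraries and 0 over the 18 others. HMRA1 held 31 to 118 counts in each of the 18 others. Its absence from rph1Δ, with HMLALPHA1 and HMLALPHA2 counts only there, is what alpha cells would give. The 0 counts of HMRA1 argue against rph1Δ cells that express the MAT locus of a cells, as the WT libraries did. The test of opposite mating type could not weigh alpha cells against an effect of RPH1 loss on mating genes. It needed an rph1Δ library at or above the lowest HMRA1 count of WT, and 0 of 6 reached it, as was known when it was chosen. These explanations were thus not told apart by that test. At 0 h 296 genes outside the mating lists were called, the deleted RPH1 and HMRA1 among them, beside 18 of 26 mating genes. Whether mating type accounts for the other changes cannot be told apart from loss of RPH1, because HMRA1 gave 0 counts in every rph1Δ library.

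The higher ribosome biogenesis transcripts of set2Δ and H3K36A at 1 h were weighed next. Library scaling was argued against, since the median against WT stayed at 0.44 (H3K36A after quantile normalization) or above (up to 1.42) in both mutants with TMM, median-of-ratios, library totals, log2 FPKM and quantile normalization. Gene length and mean expression level over all libraries were argued against as well, since both medians lay at the 100th percentile of 10000 random lists matched on these (highest 0.31 and 0.23). The low level of the list in WT at 1 h was not matched, so a dependence on it was not tested. A faster course of all genes along the WT path was argued against too. Of genes called in the mutant at 1 h that changed at least 2-fold in WT from 1 h to 3 h, 50.8% of 514 in set2Δ and 48.5% of 540 in H3K36A moved the same way (49.3% and 43.2% by chance), where the shared WT 1 h libraries by themselves raise agreement. Along the course of rph1Δ cells, which shares no library, these were 48.8% of 482 and 43.5% of 490. A faster return of this list alone stays open, since 68 of its 68 genes rose in WT over that time. The WT course from 0 h to 1 h was not used, so a course slower than WT over the first hour was not tested and stays open. A difference due to the genotypes stays open as well, untested, and the 6 H3K36A libraries also held only 5, 2, 4 and 4 counts of HHT1, HHT2, HHF1 and HHF2.

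The third pattern is a set of 159 genes at least 2-fold higher in both set2Δ and H3K36A at 0 h (232 and 204 singly, 7.28 by independent lists), with a median WT count of 18 per library. Low values in the shared WT libraries as the whole cause were argued against, since the medians of these genes against the rph1Δ libraries, which share none with WT, were 1.81 in set2Δ and 1.77 in H3K36A (lower quartiles 1.17 and 1.10), beside 1.82 and 1.81 against WT. Reads of an overlapping gene may contribute to part of it, since 36.5% of the genes (58) overlap another gene against 23.3% in matched random sets (upper bound 28.9), while 101 overlap none. A part played by low WT values stays open for some genes, as 78.6% (125 genes) were also at least 2-fold higher than in rph1Δ, between the bounds set for either answer. Greater gene length stays open too, with a median of 822 bp against 762 bp (upper bound of random sets 939). A difference due to the genotypes is a further open explanation.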

How the results depend on the processing

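The tests with library totals were chosen only after the data were seen. The number of called genes in all 21 comparisons stayed within 1.5 times its value with DESeq2, median-of-ratios scaling, library totals, no low-value filter, a mean FPKM of at least 10 and a replicate term over all libraries. The last is an alternative only, since replicate numbers do not pair the libraries: over 66 pairs of groups the correlation of replicate differences ran from -0.255 to 0.171. The 9 counts of shared changes also stayed within 1.5 times under these settings and under limma-trend.

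Counts that moved further were mostly those of rph1Δ. Its 3 h interaction, 440 genes, had 256 by limma-trend (257 and 265 with pseudocounts 0.1 and 5), 243 after quantile normalization and 664 with a replicate term within genotype. rph1Δ against WT at 3 h had 1066 genes after quantile normalization. Quantile normalization also gave shared changes of 86, 208 and 453 for rph1Δ and set2Δ at 0 h, 1 h and 3 h and 463 for rph1Δ and H3K36A at 3 h. The cause was not tested. With only the groups compared, which leaves fewer libraries for the spread, the counts were 499 and 1052 for rph1Δ at 0 h and 3 h, 656 for set2Δ at 0 h, 884 for the 1 h interaction of rph1Δ and 15 and 735 for set2Δ against H3K36A at 0 h and 3 h. Shared changes were then 270 (rph1Δ and H3K36A, 0 h), 580 (set2Δ and H3K36A, 0 h), 557 (rph1Δ and set2Δ, 3 h) and 580 (rph1Δ and H3K36A, 3 h).

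Leaving out single libraries, where a lone sample is assumed to vary like the other groups, gave these ranges of called genes. WT had 4334 to 4377 at 1 h, 4181 to 4346 at 3 h and 2466 to 2968 from 1 h to 3 h. Against WT at 0 h, 1 h and 3 h, rph1Δ had 155 to 210, 504 to 732 and 548 to 2224, set2Δ 888 to 1507, 2547 to 2616 and 2259 to 3201, and H3K36A 1022 to 1269, 2412 to 2581 and 2075 to 3035. The interactions at 1 h and 3 h had 328 to 506 and 119 to 1182 in rph1Δ, 1504 to 1989 and 1542 to 2493 in set2Δ, and 1432 to 1575 and 1257 to 2076 in H3K36A. set2Δ against H3K36A had 71 to 302, 1319 to 1452 and 85 to 157. Shared changes at the 3 times ran 53 to 144, 188 to 337 and 250 to 1515 for rph1Δ and set2Δ, 71 to 156, 232 to 403 and 281 to 1515 for rph1Δ and H3K36A, and 619 to 953, 1593 to 1816 and 1608 to 2546 for set2Δ and H3K36A.

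The balance of higher and lower genes depended on the scaling. With library totals the median log2 change of all genes went from 0.058 to 0.16 for WT at 1 h, from 0.025 to -0.245 for WT from 1 h to 3 h, from -0.047 to 0.163 for set2Δ at 1 h and from -0.063 to 0.165 at 3 h, so a small fold change is relative to the scaling. Median-of-ratios scaling gave 2322 higher and 2326 lower for WT at 1 h, 1513 higher and 1494 lower for set2Δ at 1 h, 811 higher and 820 lower and 1475 higher and 1464 lower for H3K36A at 0 h and 1 h, and 249 higher and 172 lower for the 3 h interaction of rph1Δ.

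Some results reversed, and the cause was not tested. SUI2, higher in WT from 1 h to 3 h, stood at -0.09, -0.09 and -0.087 by limma-trend (pseudocounts 1, 0.1 and 5) and -0.09 with library totals, and LPD1 in set2Δ at 3 h at 0.038 in each of these 4 and 0.052 after quantile normalization. DDI2 in the 3 h interaction of set2Δ stood at 0.062 with a pseudocount of 5. Quantile normalization reversed DLD1 (0.257) and RPN2 (0.057) in WT at 1 h, FLO9 in set2Δ at 0 h (-0.014) and 3 h (-0.051) and in H3K36A at 3 h (-0.071), PRE8 in set2Δ at 1 h (0.002), HHO1 in H3K36A at 1 h (0.028) and KGD2 in the 3 h interaction of set2Δ (0.1). It also reversed list medians: proteasome in WT from 1 h to 3 h (-0.105), in rph1Δ at 3 h (0.055) and its 3 h interaction (0.054), ribosomal proteins in rph1Δ at 0 h (0.013), set2Δ at 3 h (0.074) and set2Δ against H3K36A at 0 h (-0.016), histones in rph1Δ at 1 h (0.045), respiratory chain in H3K36A at 0 h (0.025), translation factors (-0.007) and general stress (0.094) in H3K36A at 3 h, and heat shock chaperones in the 3 h interaction of rph1Δ (0.046). Ribosomal proteins in set2Δ against H3K36A at 0 h stood at -0.038 without set2Δ 0 h replicate 1 and 0.173 without replicate 2.

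Of 960 calls of single genes, 942 were kept by DESeq2 and 15 ended (3 had no value there), 908 were kept with library totals and 50 ended, and 864 were kept after quantile normalization and 87 ended. Of 324 list calls, 317 were kept with median-of-ratios scaling, 307 with library totals and 263 after quantile normalization, but 116 with an estimated correlation, where 208 ended. On simulated data 37 of 100 genes changed by 0.5 log2 and 88 of 100 changed by 1 were called in a 3 h interaction, against 70 and 88 for set2Δ against WT at 0 h.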

Other observations

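No test here was chosen after its result was seen. Genes for histone methylation enzymes changed in WT in both directions. The demethylase genes RPH1 (1.17 ± 0.14) and JHD2 (1.43 ± 0.13) rose by 3 h in minimal medium, while the methyltransferase genes DOT1 (-0.83 ± 0.11) and SET2 (-1.22 ± 0.13), which overlaps YJL169W, fell. The list as a whole passed only for set2Δ against H3K36A at 3 h (adjusted p = 0.00606). There SET2, the gene deleted in set2Δ, was its 1 called member, so this is no result on the other members. Of the 9 genes of Rpd3S and H3K36 readers, 4 were higher in set2Δ at 1 h (adjusted p = 0.0296, but adjusted p = 0.147 with an estimated correlation), with the remodeler genes ISW1 (1.03 ± 0.08) and CHD1 (0.86 ± 0.14). Glutamate synthesis genes were lower in rph1Δ at 1 h, 6 of 9 (adjusted p = 0.000431, but adjusted p = 0.0502 with an estimated correlation), with GDH1 (-1.03 ± 0.14) the lowest. Of the 11 fatty acid synthesis genes, 6 were lower there, or 7 adjusted over the list alone (adjusted p = 0.00387, but adjusted p = 0.0862 with an estimated correlation).

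DNA damage genes rose in WT after the move to minimal medium, 14 of 17 by 3 h (adjusted p = 0.000421), led by HUG1 (4.17 ± 0.71) after DDI2, which held 1 count over the 2 libraries of 0 h and 44 at 3 h. Cell wall integrity genes responded differently in rph1Δ at 3 h, 4 of 17 higher and 1 lower, or 7 and 1 adjusted over the list alone (adjusted p = 0.00535, but adjusted p = 0.306 with an estimated correlation), with RLM1 (1.43 ± 0.31) and PIR3 (1.04 ± 0.21) the highest. RLM1 lost its call without rph1Δ 0 h replicate 1 (1.31, adjusted p = 0.0522) and without WT 3 h replicate 2 (0.96, adjusted p = 0.0587). Of the 13 unfolded protein response genes, 7 were lower and 1 higher in set2Δ at 3 h (adjusted p = 0.0274, but adjusted p = 0.0889 with an estimated correlation). Of the 27 nitrogen catabolite genes, 2 were lower in set2Δ than in H3K36A at 0 h, or 9 adjusted over the list alone (adjusted p = 0.0175, but adjusted p = 0.108 with an estimated correlation), and the call ended without set2Δ 0 h replicate 2 (adjusted p = 0.217) or H3K36A 0 h replicate 1 (adjusted p = 0.0973). Of the 22 seripauperin and mannoprotein genes, many near-identical, 8 had a lower 3 h response in set2Δ (adjusted p = 0.0303, but adjusted p = 0.199 with an estimated correlation), which ended without set2Δ 0 h replicate 1 (adjusted p = 0.072) or WT 3 h replicate 1 (adjusted p = 0.0595). Lists for zinc and copper transport, meiosis and sporulation, and silencing and telomeres passed in none of the 21 comparisons (lowest adjusted p = 0.226, 0.115 and 0.129 by camera, and 0.437, 0.277 and 0.241 with an estimated correlation).

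rph1Δ shared fewer changes with the other mutants than these did with each other, and all comparisons use the same 2 WT libraries at each time. With set2Δ at 0 h, 70 genes were higher in both and 64 lower in both (21 and 13.4 by independent lists), with 56 opposite (34.3). The 1 h counts were 111 and 263 with 238 opposite (78.5, 164 and 228 by independent lists), and at 3 h 372 and 685 with 108 opposite (155, 296 and 428 by independent lists). With H3K36A they were 88 and 82 with 39 opposite (21, 17 and 38 by independent lists) at 0 h. They were 123 and 338 with 151 opposite (76.8, 160 and 223 by independent lists) at 1 h and 358 and 724 with 81 opposite (141, 292 and 406 by independent lists) at 3 h. The covariance of the log2 changes across genes was 0.225, 0.192 and 0.269 with set2Δ at 0 h, 1 h and 3 h and 0.229, 0.242 and 0.255 with H3K36A, against 0.0263 to 0.0265 simulated for shared WT libraries and no true change. The correlations, 0.256 to 0.348, lay below the 0.499 to 0.501 of that simulation, where noise is the only variation. It gave a gene the same spread in all groups, so the wider replicate spread of WT at 3 h was not modelled. Single libraries moved these sums: for set2Δ at 0 h 53 without WT 0 h replicate 1, 87 without WT 0 h replicate 2, 60 without rph1Δ 0 h replicate 1 and 86 without rph1Δ 0 h replicate 2. At 1 h this was 191 without WT 1 h replicate 1, 220 without WT 1 h replicate 2 and 188 without rph1Δ 1 h replicate 1. At 3 h this was 250 without WT 3 h replicate 2, 561 without rph1Δ 3 h replicate 1 and 681 without rph1Δ 3 h replicate 2. For H3K36A at 0 h the sum was 71 without WT 0 h replicate 1, 112 without WT 0 h replicate 2, 79 without rph1Δ 0 h replicate 1 and 112 without rph1Δ 0 h replicate 2. Its 1 h sum was 232 without WT 1 h replicate 1, 283 without WT 1 h replicate 2 and 263 without rph1Δ 1 h replicate 1. Its 3 h sum was 281 without WT 3 h replicate 2, 569 without rph1Δ 3 h replicate 1 and 701 without rph1Δ 3 h replicate 2.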
